A study of Mus musculus with 9 samples.

How the data were processed

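Cortical neurons of C57BL/6 mouse embryos (embryonic day 15) were kept in culture for 12 days and then left untreated, given 25 µM bicuculline or given 50 mM KCl for 6 h, per the labels' protocols. Bicuculline blocks GABA-A receptors, and KCl depolarises the cells. Each of the 3 groups has 3 arrays, numbered 1 to 3 in the labels, and samples were grouped by those labels alone. Cyanine 3 labelling of 100 ng of RNA and 1-colour hybridisation to an Agilent mouse array are given in the labels' protocols. Whether the 3 replicates of a group are separate cultures is not given in the sources used here, so the p-values describe the spread between these arrays, which may be technical.

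The values used are processed signal intensity, which the authors deposited as made by Agilent Feature Extraction, version 10.7.3.1 per the file headers and version 10.5.1.1 per the submitters' processing notes. Per the file headers, this software subtracted the background and removed spatial trends within each array, and the values show that low signals carry a positive surrogate. No normalization between arrays had been applied to the deposited intensity, whose median over the features of an array was 267, 157 and 245 for control 1 to 3, 160.2, 178 and 194 for bicuculline, and 166, 171 and 149.9 for KCl. The deposited series values equalled the processed signal on all 45018 features of every array. The raw median intensity of each spot and of its local background, also deposited, served for an alternative background correction.

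The processed signal was set to log2, and the 75th percentile of the 43379 non-control spots was subtracted on each array. Spots that the software marked as outliers were left out, which removed 39 values of the genes tested, and spots of one probe were averaged. Of 41174 probes, 26888 matched a gene symbol through their RefSeq identifiers in a table of assembly GRCm38.p6, giving 18327 genes; 14286 probes did not match and are unnamed here, and identifiers listed under several symbols were left unmatched. A probe was kept if the software marked it well above background on every array of at least 1 group and it was measured on at least 2 arrays of each group. This kept 20992 named probes, and the brightest probe over all 9 arrays stood for each of the 14063 genes tested. For a gene with no array of a group well above background, the fold is given as a bound ("at least"), from the mean of the brighter group and, on each array of the dim group, the higher of the probe's value and the lowest signal marked well above background there. With such genes at their bound, the median of each list was the same to 2 decimals. Gene order from that table served only to find neighbouring genes.

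Genes were tested with limma 3.58.1 in R 4.3.3, with all 9 arrays in 1 fit, group as the only term, and Benjamini-Hochberg adjustment within each of the 3 comparisons, two-sided at an adjusted p under 0.05. The fit had 6 residual degrees of freedom and a prior of 1.76, and the number of arrays limits the precision. Every adjusted p for a gene comes from limma, errors beside a log2 fold change are limma's standard errors, and n is 3 arrays per group. The 25 gene lists, with 605 genes of which 554 were tested, were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. The lists overlap, with 631 entries, so their results are not independent. Bdnf, Inhba, Nrn1, Vgf and Scg2 are on both the effector and the neuropeptide list. Nr4a2 is also a projection neuron gene, Syt4 also a synaptic vesicle gene and Gadd45a also an apoptosis gene. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 25 lists within a comparison. Camera with an estimated correlation and fry, which tests a list without setting it against other genes, were alternatives. The lists cover immediate early transcription factors, activity-induced effectors, feedback regulators, neuropeptides and neurotrophic factors, glutamate receptors, GABA genes, voltage-gated channels, calcium genes, synaptic vesicle genes, postsynaptic genes, cholesterol synthesis and uptake, the unfolded protein response, glycolysis and hypoxia-inducible genes, heat shock and oxidative stress (heat shock for short), apoptosis and p53 targets (apoptosis), the respiratory chain with ATP synthase, neuronal markers, projection neuron identity, interneuron identity, and inflammatory and interferon-stimulated genes (inflammatory). The other 5 lists mark other cell types: astrocytes, microglia and macrophages (microglia for short), oligodendrocytes, endothelial, mural and fibroblast cells (vascular), and cycling cells and progenitors.

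Named genes are those with the 8 largest rises and falls against control whose arrays did not overlap. To these come, from each list that passed camera or had at least 3 genes passing, the 2 members with the largest change, 3 where the list passed. A panel of 10 activity genes (Fos, Fosb, Npas4, Egr1, Nr4a1, Arc, Homer1, Bdnf, Nptx2 and Gad1) is named in every comparison. For KCl against bicuculline the 6 largest in each direction were taken. Other members that are named were chosen after their values were seen. Names that are only a clone, predicted-gene or similar identifier were passed over. Some genes that the rule takes are not reported here.

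Both stimuli were compared with the same control arrays, so the overlap and correlation between them were set beside 20 simulations of unchanged groups against shared controls, and beside the overlap of independent lists. The arrays lay on 3 slides and were scanned on 1 day, per the file headers. Slide 1 held control 1 and 2 and bicuculline 1 and 2, slide 2 held control 3, bicuculline 3 and KCl 1 and 2, and slide 3 held KCl 3. Slide was fitted as a fixed and as a random block, and changes were computed within slides 1 and 2. Slide 3 holds samples of 1 group only. A block for the scan day was not fitted because all arrays share it. The labels number the replicates, and the pairing was checked by correlating the deviations of arrays from their group means. Between control and bicuculline, same-numbered arrays had r = 0.40, 0.26 and 0.74, so by a fixed rule (all above 0.1) their numbers pair them. Pairs of different number on slide 1 also deviated together (0.33 for control 1 and bicuculline 2, 0.16 for control 2 and bicuculline 1), so the pairing may follow the slides. Some arrays on different slides did so too (0.41 for control 1 and KCl 3). The deviations of a group's 3 arrays sum to 0, which ties these values to each other. The 0.41 can therefore follow from slide 2, where control 3 deviated with KCl 1 (0.27) and KCl 2 (0.32). Same-numbered arrays of KCl and the other groups had r from -0.57 to -0.09 and share only a number.

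Alternatives were quantile, median and spike-in scaling, normexp background correction (offset 50) followed by the 75th percentile or by quantile normalization, and no or a stricter filter on dim probes. Others were keeping outlier spots, the mean of a gene's probes or every probe on its own, a trended and robust prior, only the 6 arrays compared, array weights, a replicate block, stricter thresholds and leaving out each array. Normexp used the median instead of the mean signal of a spot. Spike-in scaling with 7 probes, slide as a random block and the replicate block in 6 arrays were chosen after seeing the data. The gene and list tests were tried on simulated data drawn for bicuculline against control over the same 14063 genes. The data were drawn after scaling, filtering and the choice of probes, so those steps were not tried. Genes were drawn independently, so the list test was not tried under correlation between genes. The test recovered 93 of 100 genes changed by a log2 of 1 and 81 of 100 changed by 0.5. It called 14 of 13837 unchanged genes, and 1 of 24 unshifted lists passed. Probes without a gene symbol were left out of the gene tests.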

Results

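Expression was measured on 9 arrays, with 3 each from untreated mouse cortical neuron cultures, cultures given 25 µM bicuculline for 6 h and cultures given 50 mM KCl for 6 h. The 75th percentile of the signal was 3087, 1806 and 2642 on the control arrays, 1806, 1996 and 2049.9 on the bicuculline arrays, and 1683, 1631 and 1588 on the KCl arrays. Between 65.0% and 75.9% of the non-control spots of an array were well above background, and 0 spots were saturated. Across the 14063 genes tested, the median spread between replicates was a log2 SD of 0.064. The principal component with the most variance held 65.3% of it, and the next held 16.8%.

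Bicuculline was compared with no treatment to ask which transcripts respond when GABA-A receptors are blocked. Fos rose 6.77-fold (log2 2.76 ± 0.04, adjusted p = 5.4e-09), Fosb 17.7-fold (4.14 ± 0.10, 1.1e-07) and Bdnf 7.46-fold (2.90 ± 0.03, 4.1e-09). Nptx2 rose 4.37-fold, Npas4 1.82-fold and Nr4a1 1.58-fold. Egr1 and Arc went the other way, with log2 changes of -0.59 ± 0.03 (adjusted p = 6.1e-06) and -0.65 ± 0.05 (4.0e-05). Homer1 (-0.03 ± 0.05, adjusted p = 0.64) and Gad1 (0.06 ± 0.03, 0.19) did not pass. Homer1 was read by its brightest probe, and its 2 other probes gave 0.25 each. These 2 probes carry another RefSeq transcript identifier than the brightest, so here and below they may read a different transcript of Homer1.

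**Figure D1:**
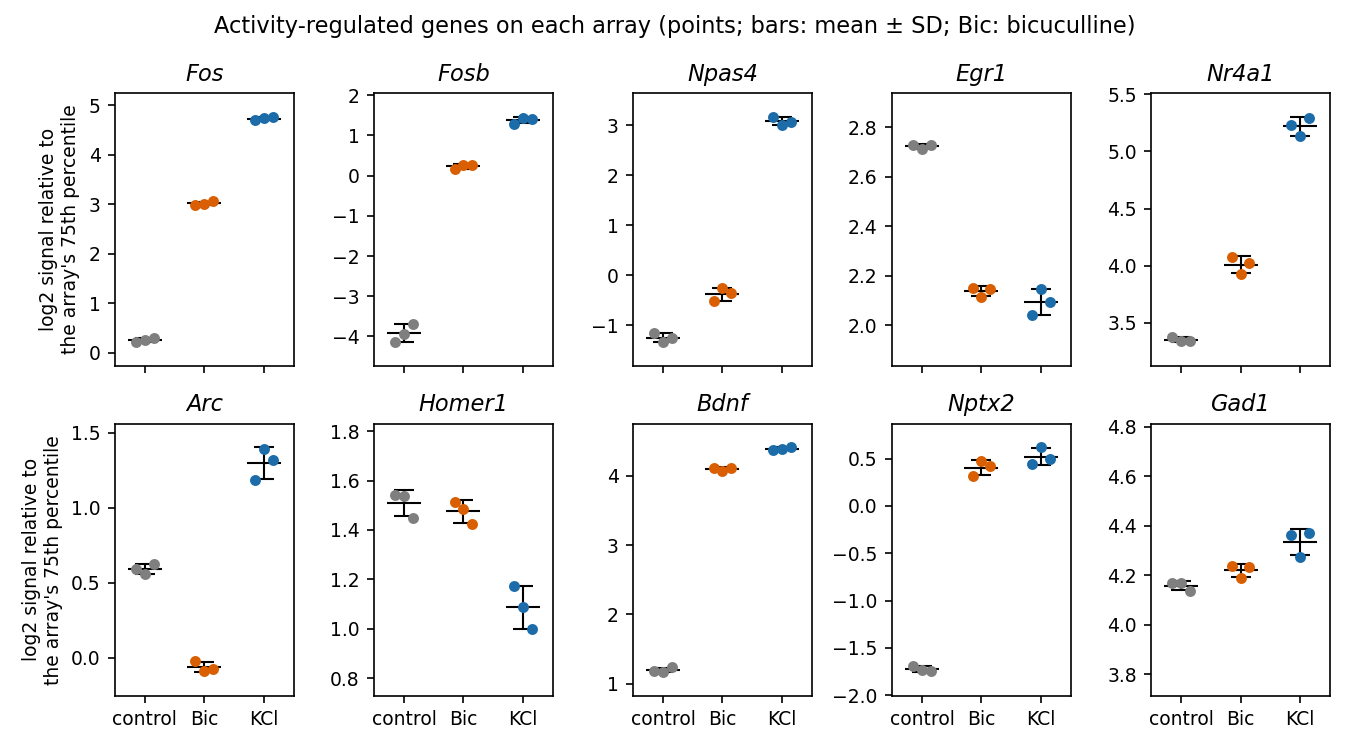
Log2 signal relative to the array's 75th percentile (vertical axes, each with its own range) of the 10 panel genes in control, bicuculline (Bic) and KCl cultures, with 1 point per array and bars for the mean ± SD of 3 arrays. Fos, Fosb, Npas4, Nr4a1, Bdnf and Nptx2 lie above control under both stimuli, Egr1 lies below under both, and Arc lies below control under bicuculline (-0.65) and above it under KCl (0.71), while Gad1 lies above control under KCl (0.18) but below it with quantile and spike-in scaling.

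Of the immediate early transcription factors, 17 rose, 4 fell and 2 did not pass of 23 measured under bicuculline, with a median log2 change of 0.87. Fosb, Fos and Atf3 (2.63) rose most, and Egr1, Egr4 (-1.05), Myc and Srf fell. Activity-induced effector genes rose in 21 cases and fell in 4 of 26, led by Ptgs2 (4.30 ± 0.05), Inhba (3.42) and Pcsk1 (2.95; 4.24 by another probe), with a median of 0.88. Arc, Arl4d, Rasgrp1 and Lingo1 were the effectors that fell. Neuropeptides and neurotrophic factors rose in 16 cases and fell in 1 of 21, with a median of 0.44. Cartpt rose most (4.13 ± 0.05), followed by Inhba and Bdnf, which are also on the effector list. Of the feedback phosphatases, kinases and signalling inhibitors, 15 rose and 3 fell of 21, with a median of 0.59, among them Dusp1 (1.74), Sik1 (1.72) and Dusp4 (1.37). Adjusted over the list alone, the counts of these 4 lists were the same, at 17 and 4, 21 and 4, 16 and 1, and 15 and 3; for every list in each comparison they equal those over all genes unless another pair is given. Camera gave the lists adjusted p = 1.5e-08, 3.7e-12, 5.3e-11 and 7.8e-07 in this order, and they also passed with an estimated correlation (0.030, 0.010, 0.020 and 0.035).

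The unfolded protein response was the remaining list to pass, with 10 genes risen and 2 fallen of 23 (12 and 5 adjusted over the list alone), a median of 0.13 and adjusted p = 0.035. That call was lost, at adjusted p = 0.46 with an estimated correlation. Leaving out control 3 (0.060) or bicuculline 1 (0.080) also ended its call. Sdf2l1 (0.95), Ppp1r15a (0.58) and Trib3 (0.54) rose most in it.

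The lists of receptors, channels and synaptic genes did not pass under bicuculline. Of the GABA genes 7 rose and 5 fell of 23 (adjusted p = 0.26), with Gabrg1 (1.26) and Gabra2 (0.94) at the top. Of the glutamate receptors 3 rose and 6 fell of 20 (0.94), with Grik2 at 0.51 (0.15 by another probe) and Grm3 at -0.47. Their median (-0.00) and the test pointed down while their mean was 0.01. Voltage-gated potassium, sodium and HCN channels rose in 6 cases and fell in 16 of 38 (0.20; 6 and 19 adjusted over the list alone), among them Kcns1 (-1.19) and Kcnc4 (-1.03). Calcium genes rose in 4 cases and fell in 15 of 37 (0.12; 4 and 16 adjusted over the list alone), with Cacna1d at -1.06 and Slc8a1 at -0.57, although other probes gave -0.67 to -0.36 for Cacna1d and -0.02 to 0.93 for Slc8a1. Of the synaptic vesicle genes 7 rose and 5 fell of 27 (0.49), with Syt4 (1.37) and Rab3c (0.88) risen; the list's median was -0.01, while its test pointed up. Postsynaptic genes rose in 6 cases and fell in 12 of 28 (0.49; 7 and 12 adjusted over the list alone), with Shank2 (1.19) and Pcdh8 risen.

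Metabolic and stress lists also did not pass under bicuculline. Cholesterol genes rose in 8 cases and fell in 7 of 25 (adjusted p = 0.49), with Pmvk (0.94) and Cyp51 (0.55) risen. Glycolysis and hypoxia-inducible genes rose in 9 and fell in 4 of 28 (0.20), with Slc2a3 (1.03) and Slc2a1 (0.54) risen. Heat shock genes rose in 7 and fell in 5 of 21 (0.26; 7 and 6 adjusted over the list alone), with Hspa1b (0.89) and Hspa1a (0.79) risen. Apoptosis genes rose in 9 and fell in 7 of 24 (0.38; 9 and 10 adjusted over the list alone), with Gadd45a (1.95) and Pmaip1 (1.35) risen. Respiratory chain genes rose in 2 and fell in 3 of 45 (0.49; 0 and 1 adjusted over the list alone), with Ndufb5 (-0.20) among those lower. Ndufb5 had adjusted p = 0.016 and did not pass without control 1 (0.057), bicuculline 1 (0.051) or bicuculline 3 (0.056), or with the replicate block in 6 arrays (0.070). Inflammatory genes rose in 2 of 14 and fell in 0 (0.11; 1 and 0 adjusted over the list alone), and the list passed with the replicate block in 6 arrays (0.029) without bicuculline 2 (0.037), and with median (0.028) and spike-in scaling (0.045).

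Neuronal markers rose in 2 cases and fell in 6 of 21 under bicuculline (adjusted p = 0.95), with Nefl (1.52) and Nefm (0.59) risen. Projection neuron genes rose in 9 and fell in 6 of 23 (0.26), with Nr4a2 (2.31) and Rorb (0.87; 1.77 by another probe) risen, and interneuron genes rose in 4 and fell in 4 of 20 (0.52; 3 and 3 adjusted over the list alone), with Gad2 and Sst (0.41 each) risen. The lists of other cell types did not pass. Astrocyte markers rose in 0 cases and fell in 5 of 17 (0.38), among them Gjb6 (-0.86) and Fgfr3 (-0.28). The 2 other probes of Fgfr3 gave -0.23 and 0.28, and the mean of all 3 did not pass (-0.08, adjusted p = 0.23). Oligodendrocyte markers rose in 1 and fell in 5 of 12 (0.66), with Olig2 at 0.31 and Mbp at -0.33. Microglia markers rose in 1 of 13 (0.66), with a median of -0.03 against a mean of 0.03. Vascular markers fell in 2 of 12 (0.69; 0 and 1 adjusted over the list alone). Cycling and progenitor genes rose in 1 and fell in 7 of 16 (0.15), with Hes5 at -0.76 and Hes1 at 0.33, where Hes1 had adjusted p = 0.032, 0.062 with the replicate block, 0.065 with a trended and robust prior, 0.056 without a filter, and 0.056 to 0.097 without any 1 of the control arrays, bicuculline 1 or bicuculline 3.

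**Figure D2:**
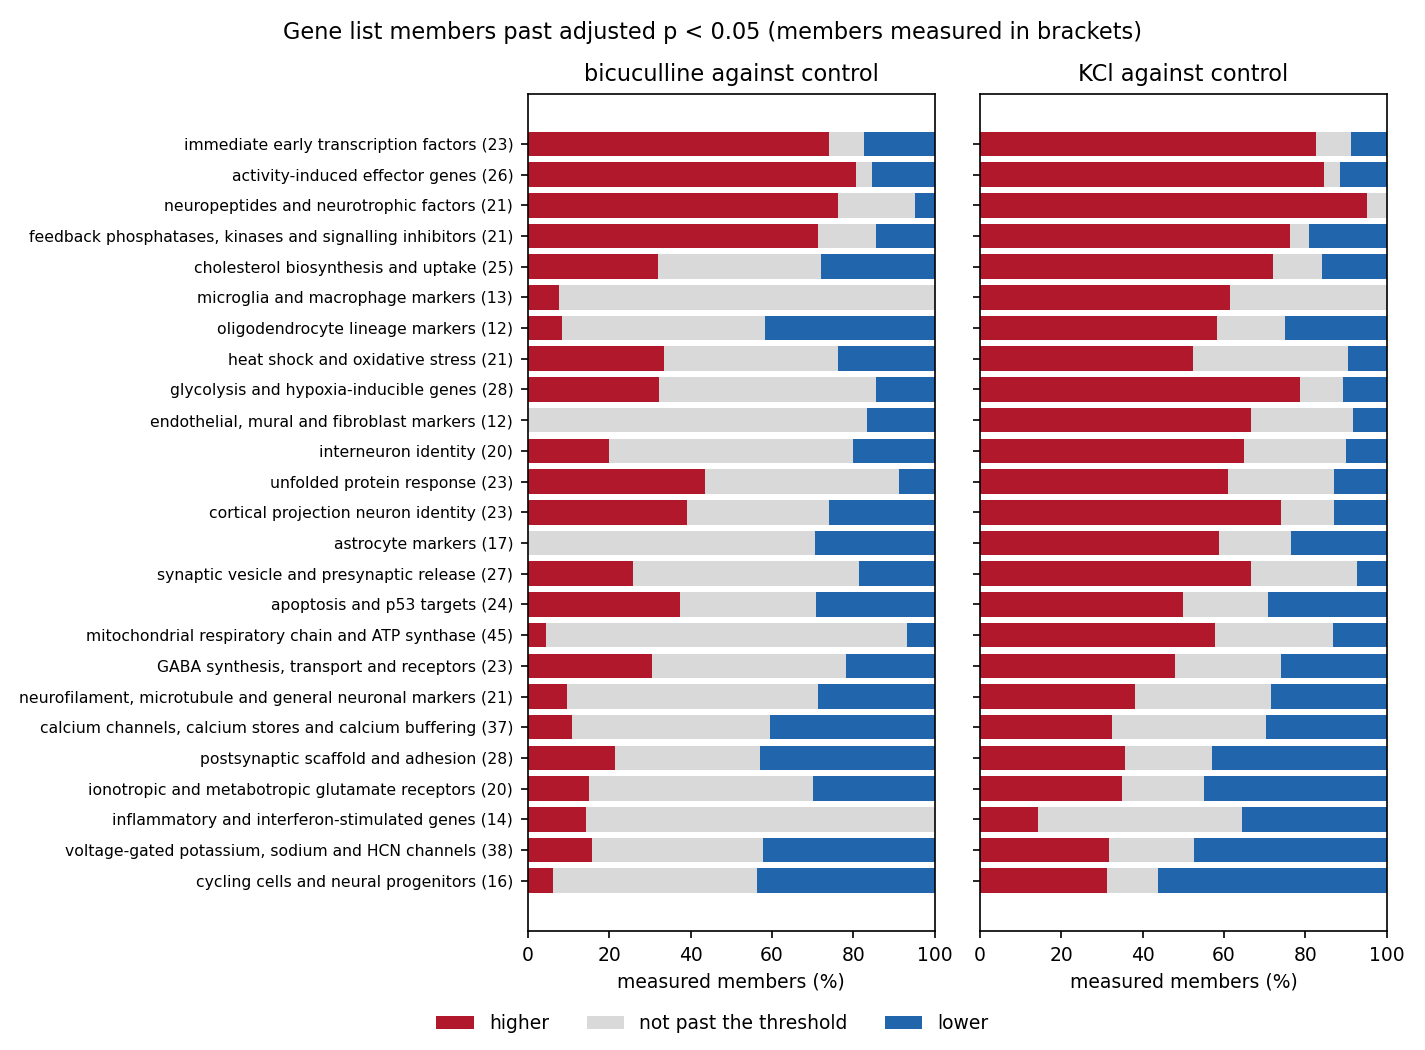
Share of each list's measured members (horizontal axis, percent; members measured in brackets) that were higher (red), lower (blue) or not past an adjusted p of 0.05 (grey) under bicuculline and under KCl, with 1 bar per list. Immediate early transcription factors had 17 of 23 members higher under bicuculline and 19 of 23 under KCl, and the respiratory chain list had 2 and 26 of 45, with a median under KCl that lay below 0 with each of the 5 other scalings.

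The largest rises under bicuculline were in genes of the late cornified envelope family. Lce1g rose at least 96.7-fold, Lce1f at least 32.3-fold and Lce1i by a log2 of 6.92 ± 0.28, with Lce1i well above background on 1 of 3 control arrays. Another probe of Lce1g rose by 3.31 and was well above background on 1 control array. Serpinb2 rose 59.5-fold (5.89 ± 0.10, adjusted p = 2.3e-08), Areg at least 14.1-fold, Tslp at least 7.1-fold and Xirp2 at least 4.6-fold. Crct1 rose at least 13.4-fold over 2 dim control arrays, with 1 control value left out as an outlier; with that spot kept the log2 change was 3.16 and did not pass (adjusted p = 0.087). The largest falls were in Gpr6 (-3.71 ± 0.16), Ebf2 (-2.51 ± 0.10), Wnt10a (-2.21 ± 0.32), Dclk3 (-2.30 ± 0.14) and Smoc2 (-2.01 ± 0.07), with Gpr6, Ebf2 and Wnt10a well above background on 1 of 3 bicuculline arrays each. Nod2 fell at least 2.0-fold, Ptx4 at least 2.1-fold and Slc28a2 at least 2.9-fold. These 8 falls did not pass with normexp and the 75th percentile (adjusted p from 0.078 to 0.90), nor did the rises of Tslp (0.13), Crct1 (0.052) and Xirp2 (0.30).

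**Figure D3:**
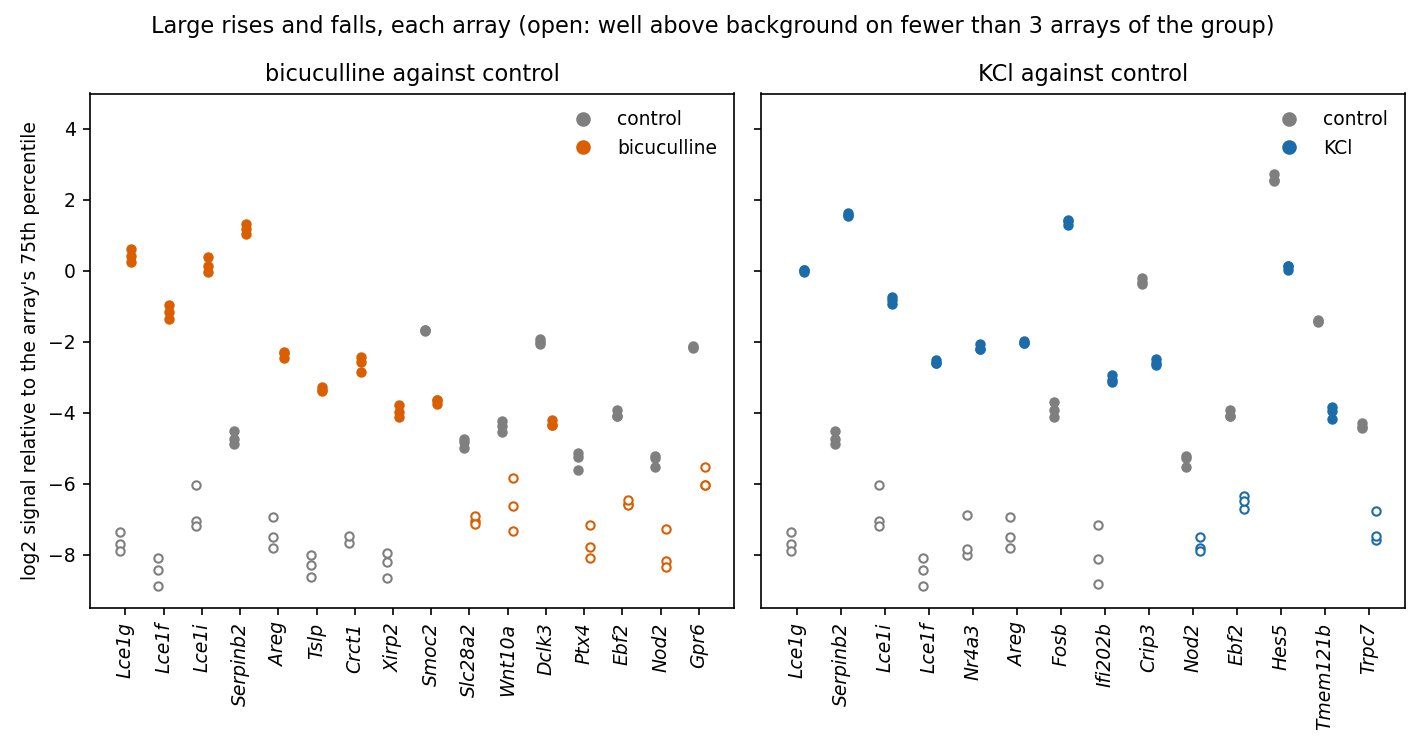
Log2 signal relative to the array's 75th percentile (vertical axis) of genes with large rises and falls under bicuculline and under KCl, with 1 point per array, open where the gene was well above background on fewer than 3 arrays of the group. Lce1g lies at least 96.7-fold above control under bicuculline and at least 72.6-fold above it under KCl.

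Under bicuculline 2446 genes were higher and 3773 lower, of which 244 and 78 changed at least 2-fold, and the median absolute log2 change of the genes called was 0.28. With slide as a block 2493 were higher and 3699 lower, 5818 of them called the same way as before, and all 5 list calls held. The sign within the slides was the same for 6219 of 6219 called genes on slide 1 and 6216 of 6217 on slide 2, and the immediate early list had medians of 0.85 and 0.89 there. The genes were called on these same arrays, so such agreement in sign, here and below, is largely built in and is no independent check. The share of calls that were higher was 39.3%, against 59.2% with normexp and the 75th percentile and 49.9% with spike-in scaling. Far fewer genes were called there, with 484 higher and 334 lower in the former and 1232 and 1235 in the latter. Of the smaller changes given above, those of Sik1, Grik2, Kcns1, Cacna1d, Shank2, Slc2a1, Ndufb5, Rorb, Gad2, Sst, Gjb6, Fgfr3, Mbp and Hes1 did not pass with normexp and the 75th percentile, nor those of Ndufb5, Fgfr3 and Hes1 with spike-in scaling.

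KCl was compared with no treatment to ask which transcripts respond to direct depolarisation. Fos rose 22.1-fold (log2 4.47 ± 0.04, adjusted p = 5.2e-10), Fosb 39.3-fold (5.30 ± 0.10, 1.1e-08) and Npas4 by a log2 of 4.32 ± 0.08 (9.0e-09). Bdnf rose 9.12-fold (3.19 ± 0.03), Nptx2 4.74-fold, Nr4a1 3.64-fold and Arc 1.63-fold (0.71 ± 0.05, adjusted p = 7.8e-06). Egr1 fell, with -0.63 ± 0.03 (1.1e-06). Homer1 was lower on its brightest probe (-0.42 ± 0.05, 1.5e-04), while its 2 other probes gave 0.53 and 0.67. Gad1 rose by 0.18 ± 0.03 (2.0e-03), but lay below control with quantile and spike-in scaling.

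Of the immediate early transcription factors, 19 rose and 2 fell of 23 under KCl (20 and 2 adjusted over the list alone), with a median of 1.74 and adjusted p = 3.0e-07. Nr4a3 rose at least 16.2-fold, and Egr1 and Myc were those that fell. Activity-induced effectors rose in 22 cases and fell in 3 of 26 (22 and 3 adjusted over the list alone; median 1.30, 1.0e-08), led by Pcsk1 (4.08; 6.37 by another probe), Ptgs2 (3.66) and Inhba (3.29). Rasgrp1, Arl4d and Homer1 fell, where Homer1 fell on its brightest probe only and its other probes were above control. Neuropeptides and neurotrophic factors rose in 20 of 21 cases (median 0.96, 1.0e-08), with Cartpt at 4.45 ± 0.05. These 3 lists also passed with an estimated correlation (0.046, 0.025 and 0.037). Feedback regulators rose in 16 cases and fell in 4 of 21 (median 0.70, 5.4e-04), with Dusp4 (2.61), Dusp1 (2.33) and Sik1 (2.16), and had adjusted p = 0.10 with an estimated correlation.

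Of the synaptic vesicle genes 18 rose and 2 fell of 27 under KCl (20 and 3 adjusted over the list alone), with a median of 0.18 and adjusted p = 0.0067. Rab3c (1.83) and Syt4 (1.74) rose most, and the list had adjusted p = 0.34 with an estimated correlation. It did not pass with quantile normalization (0.066), normexp and the 75th percentile (0.34), normexp and quantile normalization (0.064) or spike-in scaling (0.063), where its median turned to -0.05. Voltage-gated channels went both ways, with 12 risen and 18 fallen of 38 (0.53), among them Kcnf1 (1.30) and Kcnh7 (1.04). Of the calcium genes 12 rose and 11 fell of 37 (0.81); their median was 0.02 and their mean -0.00. Cacna1d was at -1.68 and Slc8a1 at -0.76, while other probes gave -0.92 to 0.29 for Cacna1d and -0.46 to 2.13 for Slc8a1. Glutamate receptors rose in 7 cases and fell in 9 of 20 (0.83), with Grik3 up at least 2.2-fold and Grin2d at 0.80; the median was -0.07 and the mean 0.14. GABA genes rose in 11 and fell in 6 of 23 (0.25), with Gabrg1 (1.38) and Gabra2 (1.00). Postsynaptic genes rose in 10 and fell in 12 of 28 (0.83; median -0.03, mean 0.09), with Pcdh8 (2.12) and Shank2 (1.68).

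Cholesterol genes rose in 18 cases and fell in 4 of 25 under KCl (median 0.56, adjusted p = 0.0031), with Pmvk (1.28) and Sc5d (1.24) among those risen. Of the glycolysis and hypoxia-inducible genes 22 rose and 3 fell of 28 (median 0.31, 6.3e-04), with Adm (1.49), Slc2a3 (1.46) and Slc2a1 (0.91). These lists had adjusted p = 0.45 and 0.34 with an estimated correlation, and the latter 0.15 with normexp and the 75th percentile. The unfolded protein response rose in 14 cases and fell in 3 of 23 (median 0.23, 0.037), led by Ppp1r15a (1.16), Sdf2l1 (0.83) and Atf4 (0.81). Heat shock genes rose in 11 and fell in 2 of 21 (median 0.33, 0.045), led by Hspa1b, Bag3 (1.06) and Hspa1a (0.99). They had adjusted p = 0.38 and 0.47 with an estimated correlation, and heat shock had 0.052 with slide as a block. The unfolded protein response did not pass without control 3 or KCl 1 (0.055 each), nor heat shock without control 3 (0.058) or KCl 3 (0.076). The unfolded protein response passed with 0 of the 5 other scalings (adjusted p from 0.059 to 0.47), with a median of 0.01 in spike-in scaling. Heat shock did not pass with quantile normalization (median 0.06, 0.13), normexp and quantile normalization (median 0.07, 0.090), normexp and the 75th percentile (0.15) or without a filter (0.057). Respiratory chain genes rose in 26 and fell in 6 of 45 (median 0.16, adjusted p = 0.046), with Atp5b (0.52), Atp5d (0.51) and Uqcrq (0.38). The 2 other probes of Atp5b gave 0.10 and 0.08, and it did not pass with quantile normalization (0.17, adjusted p = 0.053). That call was lost with slide as a block (0.052) and had adjusted p = 0.70 with an estimated correlation, and its median lay below 0 with the 5 other scalings. It also did not pass without control 1 (0.068), control 3 (0.081), KCl 1 (0.059) or KCl 3 (0.079). Apoptosis genes rose in 12 and fell in 7 of 24 (0.31), with Gadd45a (1.96) and Pmaip1 (1.61). Inflammatory genes rose in 2 and fell in 5 of 14 (0.83), with Il1b at 2.04 (well above background on 1 of 3 control arrays) and Cxcl10 at -1.46.

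Projection neuron genes rose in 17 cases and fell in 3 of 23 under KCl (median 0.22, adjusted p = 0.0033), with Nr4a2 (3.46), Fezf2 (1.86) and Sox5 (1.92, well above background on 2 of 3 control arrays). Interneuron genes rose in 13 and fell in 2 of 20 (median 0.25, 0.013), with Nos1 (1.05, likewise on 2 of 3), Sst (0.86) and Dlx6 (0.85). They had adjusted p = 0.10 and 0.26 with an estimated correlation, and interneuron genes 0.25 with normexp and the 75th percentile and 0.054 with spike-in scaling. In spike-in scaling the medians of these lists were -0.01, where the former passed (0.011), and 0.02. Neuronal markers rose in 8 and fell in 6 of 21 (0.53), with Nefl at 1.42 and Nefh at -1.02. Among other cell types, vascular markers rose in 8 cases and fell in 1 of 12 (median 0.30, 0.036), led by Tagln (1.27), Vtn (1.07) and Kdr (0.67), with adjusted p = 0.17 with an estimated correlation and 0.062 without control 2. Their list did not pass with quantile normalization (median 0.12, 0.094) or normexp and quantile normalization (median 0.14, 0.091). Microglia markers rose in 8 of 13 (7 adjusted over the list alone; median 0.54, 0.054), among them Cd14 (1.78) and Fcer1g (0.71; 0.069 with slide as a block). The microglia list passed with each of the 5 other scalings and without bicuculline 1 (0.034), bicuculline 2 (0.040) or KCl 1 (0.010). Astrocyte markers rose in 10 and fell in 4 of 17 (0.25), with Gfap at 0.66 and Gjb6 at -0.69 (0.063 with slide as a block). Oligodendrocyte markers rose in 7 and fell in 3 of 12 (0.13; 8 and 3 adjusted over the list alone), with Olig2 at 0.44 and Mag at 0.60, which did not pass without control 1 (0.068), KCl 1 (0.067) or KCl 2 (0.059), or with spike-in scaling (0.38, adjusted p = 0.060). Cycling and progenitor genes rose in 5 and fell in 9 of 16 (0.72), with Hes5 at -2.52 ± 0.06 and Hes1 at 0.69.

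The largest rises under KCl were in Lce1g (at least 72.6-fold; log2 2.00 by another probe), Serpinb2 (78.3-fold, log2 6.29 ± 0.10, adjusted p = 6.3e-09), Lce1i (5.93 ± 0.28), Lce1f (at least 12.1-fold), Nr4a3, Areg (at least 17.8-fold), Fosb and Ifi202b (at least 8.7-fold). Among the largest falls were those of Tmem121b (-2.58 ± 0.07), Hes5 and Crip3 (-2.27 ± 0.06). Trpc7 fell at least 2.8-fold, Ebf2 at least 3.6-fold and Nod2 at least 1.4-fold. Trpc7, Ebf2 and Nod2, all dim under KCl, and the astrocyte gene Gjb6 lay above control with normexp and the 75th percentile. Of the other genes given for KCl, Tmem121b, Grik3, Grin2d, Kcnh7, Cacna1d, Atp5b, Atp5d, Uqcrq, Nos1, Gfap, Mag, Vtn, Hes1, Il1b and Gad1 did not pass there, nor Uqcrq and Gad1 with any of the 5 other scalings.

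Under KCl 5026 genes were higher and 5074 lower, 71.8% of those tested, of which 820 and 399 changed at least 2-fold. With slide as a block 4258 were higher and 4548 lower, 8516 of them called the same way as before, and 10095 of 10096 called genes had the same sign within slide 2, where the immediate early list had a median of 1.79. The share of calls that were higher was 49.8%, against 31.3% with median scaling and 25.7% with spike-in scaling, which moved the median of all genes to -0.14 and -0.20 from 0.02 and that of each list down with it.

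Bicuculline and KCl changed 4609 genes the same way, 1892 higher and 2717 lower, where independent lists would share 874 and 1361. Another 277 genes were higher under bicuculline and lower under KCl, and 348 lower under bicuculline and higher under KCl, where independent lists would share 883 and 1348. Of the 4609 genes, 3586 (77.8%) changed more under KCl, with median absolute log2 changes of 0.53 under KCl and 0.30 under bicuculline. Across genes, which are not independent replicates, the log2 changes correlated with Pearson r = 0.716 and Spearman rho = 0.622. Unchanged groups simulated against shared controls gave r = 0.495 and rho = 0.454. The simulated arrays were independent of each other, while real arrays of one slide could deviate together (r = 0.74 for control 3 and bicuculline 3). The covariance was 0.190 against 0.0087 simulated. The simulated values already hold the shared controls, at the spread between these arrays. If that spread is only technical, the shared controls could add more. The 3 control arrays cannot be divided into parts of at least 2 each, so this was not tested. Part of the excess may also come from shared slides, which the simulation left out.

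**Figure D4:**
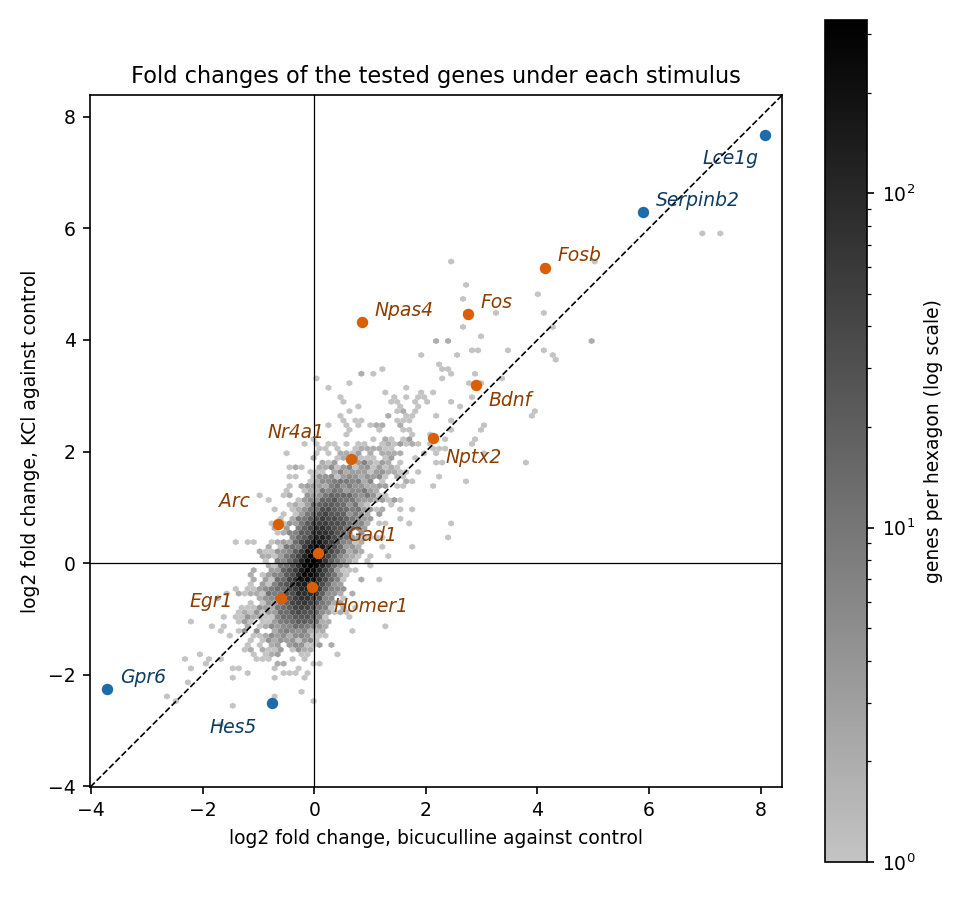
Log2 fold change against control under bicuculline (horizontal axis) and under KCl (vertical axis) for the 14063 genes tested, shaded by the number of genes per hexagon, with panel genes in orange, other named genes in blue (Lce1g, dim in control, at its fitted value) and a dashed line where both changes are equal. The values correlated with r = 0.716 across genes, Npas4 lies far above the dashed line (0.87 and 4.32), and Arc is lower under bicuculline and higher under KCl.

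KCl was compared with bicuculline directly to test which changes differed between the stimuli. Npas4 was 11.0-fold higher under KCl (log2 3.46 ± 0.08, adjusted p = 3.6e-07). Fos (1.71 ± 0.04, 3.0e-07), Arc (1.36 ± 0.05, 9.4e-07), Nr4a1 (1.21 ± 0.05) and Fosb (1.15 ± 0.10) were higher under KCl too, and Bdnf by a smaller 0.29 ± 0.03 (8.2e-05). Bdnf did not pass with normexp and the 75th percentile (0.10, adjusted p = 0.67), normexp and quantile normalization (0.10, 0.051) or spike-in scaling (0.06, 0.63). Egr1 (-0.04 ± 0.03, adjusted p = 0.27) and Nptx2 (0.12 ± 0.06, 0.11) did not pass, although Egr1 was lower with median (-0.17, 0.032) and spike-in scaling (-0.27, 0.049). Homer1 was lower by its brightest probe (-0.39 ± 0.05), while its 2 other probes gave 0.28 and 0.42. Gad1 was at 0.12 ± 0.03 (0.018; 0.13 with slide as a block, 0.061 without bicuculline 2, and 0.056 without KCl 1 or KCl 3), and lay below 0 with quantile, median and spike-in scaling. Nr4a3 was higher by 2.98 ± 0.26, Smad9 at least 4.0-fold (log2 SD of the KCl arrays 1.55), Ptger4 at least 3.2-fold, Pth at least 2.8-fold and Atf7ip2 at least 2.3-fold. Crip3 (-2.00 ± 0.06), Fbxo15 (-1.89 ± 0.18) and Dus4l (-1.84 ± 0.07) were lower under KCl, Sox13 at least 2.5-fold and Sprr2h at least 2.3-fold. Fbxo15, Sox13 and Sprr2h, all dim under KCl, were higher under KCl with normexp and the 75th percentile, where Smad9, Ptger4, Pth, Atf7ip2 and Dus4l did not pass.

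Immediate early transcription factors were higher under KCl than under bicuculline in 18 cases and lower in 3 of 23 (median 0.92, adjusted p = 3.1e-04). Effectors were higher in 16 and lower in 3 of 26 (0.0062; 17 and 3 adjusted over the list alone), and neuropeptides and neurotrophic factors higher in 15 and lower in 3 of 21 (0.0096; 17 and 3). Cholesterol genes were higher in 21 and lower in 2 of 25 (median 0.38, 0.0013), and glycolysis and hypoxia-inducible genes in 22 and 2 of 28 (median 0.26, 0.0028). Projection neuron genes were higher in 16 and lower in 1 of 23 (median 0.30, 0.0028), and interneuron genes in 15 and 0 of 20 (16 and 0 adjusted over the list alone; median 0.24, 0.013). Synaptic vesicle genes were higher in 19 and lower in 2 of 27 (20 and 2 adjusted over the list alone; median 0.18, 0.0030), and calcium genes in 19 and 4 of 37 (median 0.14, 0.039), both with medians below 0 under spike-in scaling. Of other cell types, astrocyte markers were higher in 12 and lower in 2 of 17 (13 and 2 adjusted over the list alone; median 0.24, 0.039), and vascular markers in 8 and 0 of 12 (median 0.28, 0.043; 0.055 with slide as a block). With an estimated correlation 0 of the 11 lists passed in camera, with adjusted p from 0.19 to 0.34, and 4 of the 25 had an unadjusted p under 0.05. Calcium genes, astrocyte markers and vascular markers did not pass without bicuculline 3 (0.059, 0.059 and 0.058). With the 5 other scalings calcium genes (adjusted p from 0.15 to 0.58) and astrocyte markers (0.063 to 0.71, medians from 0.02 to 0.12) did not pass, nor vascular markers with quantile normalization (0.090) or normexp and quantile normalization (0.089). With normexp and the 75th percentile effectors (0.12), synaptic vesicle genes (0.54), glycolysis and hypoxia-inducible genes (0.54) and interneuron genes (0.24) did not pass either. Glycolysis and hypoxia-inducible genes also had 0.051 with normexp and quantile normalization, and synaptic vesicle and interneuron genes 0.071 and 0.053 with spike-in scaling. Medians of lists that passed in spike-in scaling were smaller there, with 0.15 for cholesterol, 0.10 for effectors, 0.07 for projection neuron and 0.03 for glycolysis and hypoxia-inducible genes.

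Among the lists that did not pass between the stimuli, feedback regulators were higher in 12 cases and lower in 5 of 21 (adjusted p = 0.11) and microglia markers higher in 7 of 13 (0.059). Respiratory chain genes were higher in 17 and lower in 2 of 45 (0.059; 16 and 2 adjusted over the list alone), and inflammatory genes higher in 2 and lower in 7 of 14 (median -0.52, 0.099). The microglia, respiratory chain, heat shock and inflammatory lists passed without bicuculline 2 (0.016, 0.044, 0.049 and 0.046), the microglia list without KCl 1 (0.012) and with each of the 5 other scalings, and the respiratory chain list without control 1 (0.037), control 2 (0.034) or KCl 2 (0.049). Heat shock genes (0.092), oligodendrocyte markers (0.088), voltage-gated channels (0.28), apoptosis genes (0.30), GABA genes (0.37) and the unfolded protein response (0.37) did not pass. Postsynaptic genes (0.39), cycling and progenitor genes (0.59), neuronal markers (0.68) and glutamate receptors (0.73) did not pass either. Adjusted over the list alone, oligodendrocyte markers were higher in 8 and lower in 1 of 12 (7 and 1 over all genes), channels in 15 and 6 of 38 (16 and 6), and neuronal markers in 6 and 4 of 21 (7 and 4).

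Between KCl and bicuculline 5040 genes were higher and 4065 lower, of which 311 and 176 differed at least 2-fold. Of the 4866 genes called against control under KCl only, 4063 also differed here, as did 761 of the 985 called under bicuculline only. With slide as a block 3843 were higher and 3456 lower, 7069 of them called the same way as before, and 9105 of 9105 called genes had the same sign within slide 2. The share of calls higher under KCl was 55.4%, against 42.8% with quantile, 33.7% with median and 19.5% with spike-in scaling, 44.4% with normexp and the 75th percentile and 43.3% with normexp and quantile normalization.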

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

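The tests of epidermal cells, of a shared transcript, of slide, of array scaling and of background correction were set only after the results were seen. The settings for slide, scaling and background that they use had been fixed before, except spike-in scaling. Those of the spread between arrays, of the probes of Egr1 and Arc and of other splits were set before.

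Probes without a gene symbol lie outside the gene tests, and some stood above control. Of the 6789 such probes that passed the filter, 185 were at least 2-fold above control under bicuculline and 615 under KCl. The largest of these rises were log2 lower bounds of 3.24 and 4.40.

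Late cornified envelope genes, best known from skin, rose under both stimuli: of 14 on the array 8 were tested, and 5 were higher under bicuculline and 8 under KCl, on risen probes whose direction was the same with the 5 other scalings. Among all 14063 genes tested, 2446 and 5026 were higher. Only Lce1b and Lce1l were well above background on all 3 control arrays, so the other tested genes entered only through treated arrays, which favours rises. Lce1b and Lce1l did not pass under bicuculline (0.08 and -0.18) and were higher under KCl (0.75 and 0.63). The count of 5 under bicuculline therefore rests on genes admitted by the treated arrays. The tables argue against 1 transcript read by all the probes. Among the 7 probes risen under both stimuli, the difference between KCl and bicuculline ran from -1.41 (Lce1f) to 0.85 (Lce3c). The gap was 2.26 ± 0.40 (SE from the arrays, not limma's), taken as the largest with no allowance for that choice. The risen Lce1 probes were all lower under KCl, from -1.41 (Lce1f, SE 0.12) to -0.41 (a probe of Lce1g, SE 0.11), so they also differed in size. A difference in sign rests on the Lce3c probes (0.85 and 0.41), and the latter did not pass (limma, adjusted p = 0.45). Epidermal cells stay open for both stimuli, since the 15 measured of 35 epidermal markers, 1 of the 35 also on another list, went both ways: their median log2 change was -0.13 (SE 0.32) under bicuculline, with Krt6a (2.81), Sprr1a (1.72) and Lypd3 (1.29) risen but Krt5 (0.02), Krt14 (-0.17) and Dsp (-0.47) not, and 0.46 (SE 0.33) under KCl, with Krt5 at 0.92. Of the 15 markers 11 were well above background on all control arrays, which would hide a small share of such cells. A response of the cultures and partial cross-hybridisation among Lce1 probes stay open as untested explanations.

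Most genes tested (71.8%) were called under KCl. As the source of this number, the tables argue against slide, with 8806 genes called with slide as a block, and against array scaling, with 8478 under spike-in scaling, the fewest among quantile, median and spike-in scaling. Such totals do not cover direction, which did depend on scaling. Spike-in scaling gave 2177 higher and 6301 lower, and 7248 of the 10100 genes were called the same way. Background correction stays open in part: 4139 genes were called with normexp and the 75th percentile, where the residual SD rose to 0.175 from 0.064, and 9329 with normexp and quantile normalization. This test was divided from that of scaling after the result was seen, because normexp changes the background. A small spread between arrays that may be technical, which lets small changes pass, also stays open, since 66.2% of the calls were under 1.5-fold, as does a response to depolarisation.

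Egr1 and Arc were lower under bicuculline while Fos, Fosb and Bdnf were higher. The tables argue against array scaling, since the change nearest to 0 of either gene under another scaling was -0.57, and both passed under each. They argue against slide, with -0.58 as the change nearest to 0 within a slide. A fault of a probe stays open, since the array has 2 probes for them in total, 1 for each gene. A response to the stimulus that differs between these genes was not tested.

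Other splits of the samples were set against the real one. For bicuculline against control, KCl against control and KCl against bicuculline, the real split called 6219, 10100 and 9105 genes and the highest other called 0 (limma; up to 659, 593 and 644 genes had an unadjusted p under 0.05), so 1 of 10 splits gave as many in each, and 10 splits are too few for a share under 0.05. For bicuculline, where numbers pair the arrays, 4 splits part all 3 pairs and the others part fewer, and the highest other was 0 in both kinds. For the comparisons that use 3 groups, 100 of 840 splits were drawn. As many genes changed the same way by both stimuli as in the real split (4609) came from 2 of 100. The other split gave 5887, with the 3 KCl arrays as the reference, which is the structure of the samples itself. The next highest gave 79 and the remaining splits 0. These splits mix treatments within groups and leave slide pairs aside, so treatment differences widen their spread and few genes can pass. The count therefore does not exclude chance, nor a share that comes from the common controls. A correlation as high as 0.716 came from 42 of 100 (highest other 0.958), and as many list calls as 29 of 75 from 13 of 100 (highest other 38), so chance cannot be excluded for these by such counts, as the splits hold treated arrays whose differences also enter r and the list calls.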

How the results depend on the processing

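Spike-in scaling, slide as a random block and the replicate block in 6 arrays were chosen only after the data were seen. Of 168 values of named genes 79 kept direction and call under all 29 settings run for them, as did 19 of 75 list results under all 30; the cause of the changes below was not tested unless it is named. A fold of at least 2, by its construction, left 244 and 78 genes under bicuculline, 820 and 399 under KCl, 311 and 176 between the stimuli, and 272 genes changed the same way. An adjusted p under 0.01 left 19 list calls and 0 for other cell types, against 29 and 3. Camera with an estimated correlation gave 7 and 0 (4, 6 and 4 lists and 0, 1 and 1 of other cell types at an unadjusted p under 0.05 in the 3 comparisons), and fry, which does not compare a list with other genes, 63 and 12. With median scaling 1542, 2889 and 2468 genes were higher in the 3 comparisons, and Gad1 was at -0.0060 between the stimuli. With quantile normalization Gad1 was at -0.0044 under KCl and -0.065 between the stimuli, and the respiratory chain list at -0.058 under KCl. With normexp and the 75th percentile 484 genes were higher and 334 lower under bicuculline, 1825 and 2314 under KCl, 1074 and 1347 between the stimuli, 710 changed the same way, r was 0.524 and 19 list calls passed. In it the respiratory chain list was at -0.019, Trpc7 at 0.36, Ebf2 at 0.16, Nod2 at 0.70 and Gjb6 at 0.70 under KCl, and Sprr2h at 0.64, Fbxo15 at 0.18 and Sox13 at 0.60 between the stimuli, and 47 further named values lost their call. With normexp and quantile normalization the respiratory chain list was at -0.084. Spike-in scaling gave 1232 and 1235 genes under bicuculline, 2177 higher under KCl, 1261 higher between the stimuli and 2021 changed the same way, with Gad1 at -0.049 under KCl and -0.11 between the stimuli. Without a filter r was 0.605, among genes above the median signal 0.759, and with the stricter filter on dim probes 0.699. The mean of all probes put Slc8a1 at 0.091 and 0.15 and Homer1 at 0.15, 0.26 and 0.10. Every probe on its own gave 5 other cell type calls, Homer1 at 0.25, 0.67 and 0.42 and Slc8a1 at 2.13 under KCl, since other probes of these genes read otherwise.

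With the replicate block 2362 genes were higher and 3602 lower under bicuculline, 4948 and 5014 under KCl and 4950 and 4012 between the stimuli; with the block in 6 arrays the counts were 2647 and 3872, 4319 and 4584, and 4349 and 3540. Among named genes and lists under bicuculline, the block changed the calls of Hes1, Ndufb5 and the inflammatory list only. For KCl, where arrays share only a number and not every array correlates best with its own, the microglia list passed with the block (0.031 against control, 0.030 between the stimuli) and the vascular list did not between them (0.062). In 6 arrays the block also ended the calls of Grin2d (0.052) and Gad1 between the stimuli (0.055). Leaving out each array in turn moved r from 0.647 (without bicuculline 3) to 0.750 (without control 3), and the other cell type calls from 1 (without bicuculline 3) to 5 (without bicuculline 2), while the gene counts stayed within 1.5 times. A block for the scan day was not run.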

Other observations

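The tests in this part were set before their results were seen, except the check of families under other scalings.

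Genes that rose at least 2-fold may lie next to each other more often than random genes do, with order taken from a table of assembly GRCm38.p6 and pairs of one name stem left out. Under bicuculline 11 neighbouring pairs had both risen among 244 genes, against a mean of 3.98 and a highest draw of 13 in 10000 random draws (1-sided permutation p = 0.0023, adjusted over the 2 tests 0.0023). Under KCl there were 73 pairs among 820 genes, against a mean of 45.1 and a highest draw of 72 (1-sided permutation p = 0.0001, the smallest these draws can give; adjusted 0.0002). Pairs included Pla2g4a (2.36) with Ptgs2 (4.30), Baiap2l1 (2.97) with Nptx2 (2.13), and Pcsk1 (2.95) with Ell2 (1.74) under bicuculline. Foxf2 with Foxc1 and Lce3c with Crct1 were also counted, as only pairs of one name stem were left out. The order ran over the 14063 genes tested, so genes that were not tested can lie between the members of a pair. Shared regulation and transcripts that run on into the next gene are candidate explanations that were not told apart, and others were not examined.

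Whether genes that share a name stem shift together was tested with camera on 158 families of at least 10 genes. Under bicuculline 0 families and under KCl 0 families passed with both the preset and the estimated correlation after adjustment (camera), and 4 and 8 had an unadjusted p under 0.05 with the estimated correlation. With the preset correlation alone 1 family passed under bicuculline, Pcdh protocadherins (8 risen and 0 fallen of 10), and 17 under KCl. Pcdhb protocadherins were counted apart, with 0 risen and 7 fallen of 21 under bicuculline (median -0.15, adjusted p = 0.21). Under KCl, zinc finger genes (Zfp) rose in 54 cases and fell in 208 of 314 (median -0.34, adjusted p = 2.0e-05, 0.46 with an estimated correlation), while ribosomal protein genes (Rpl) rose in 40 of 47 (median 0.31, 0.65 with an estimated correlation). Mitochondrial ribosomal genes (Mrpl) fell in 32 of 49 (median -0.19), Exosc genes in 10 of 10 and Mcm genes in 9 of 10 under KCl. Larger medians under KCl were those of Pcdh (1.22) and of olfactory receptor genes (Olfr, 0.84), against 0.02 for all genes. For Olfr the median was 0.26 with normexp and quantile normalization and 1.23 with normexp and the 75th percentile. The cause of these rises was not tested. The medians of these families under KCl had the same sign with each of the 5 other scalings, but sizes moved: with these, Rpl ran from 0.06 (quantile normalization) to 0.14 (median scaling), Mrpl from -0.42 (spike-in scaling) to -0.27 (normexp and quantile normalization), and Zfp from -0.56 (spike-in scaling) to -0.06 (normexp and the 75th percentile).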
